A study of Homo sapiens with 12 samples.

How the data were processed

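Messenger RNA was measured by sequencing in 12 libraries of PC9-OR cells, 3 in each of 4 treatment groups: Control, osimertinib (OSI), dauricine (DAC) and both compounds (DAC+OSI). The labels describe poly(A) enrichment with oligo(dT) beads, fragmentation, priming with random hexamers and PCR amplification. They do not say whether the protocol kept the strand, so reads of antisense genes cannot be told from reads of the genes they overlap. The deposited values are raw counts of reads per Ensembl gene for 39266 genes. The submitters name CASAVA, HISAT2 and featureCounts without versions or settings. The genome build and the annotation are not given in the sources used here, so no coordinates are printed. Gene symbols came from a table of gene names, which held 39178 of the identifiers. Gene types, GC content and lengths came from GENCODE 29, which held 37919 of them, and 7 were in neither.

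Total counts per library ran from 24.9 to 66.9 mega-counts (M). A count of 0 therefore allows a level of up to 3 counts, which is 0.0449 to 0.12 CPM (counts of a gene per M counts of its library) depending on the library. Reads amplified by PCR without molecular identifiers are not independent molecules, so these floors cover counting error only. Nothing in the labels says whether the 3 libraries of a group come from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

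Low counts were removed with filterByExpr of edgeR 4.0.16, which left 20820 genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood negative binomial model of edgeR was fitted to all 12 libraries with 1 mean per group. The biological coefficient of variation was 20.9%. All tests were two-sided, with p-values adjusted over the genes tested by the Benjamini-Hochberg method within each of 6 comparisons, and a gene was called at an adjusted p under 0.05. The comparisons were OSI, DAC and DAC+OSI each against Control, DAC+OSI against OSI, DAC+OSI against DAC, and the interaction, which is the effect of DAC in the presence of OSI minus its effect without OSI. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. Levels are CPM on the TMM scale as mean ± SD over the 3 libraries of a group, and mean log2 CPM of gene lists used a prior count of 2. Computations ran in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0.

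Before the data were examined, 44 gene lists, 14 genes of interest, the comparisons and most of the alternatives were fixed. Each list with at least 5 tested members was tested with camera of limma, which compares the list with all other genes, at its preset correlation of 0.01 and with adjustment over the 44 lists. Camera was also run with a correlation estimated from the data, and fry of limma was run beside it. The p of fry tests whether the genes of a list move on balance one way, its mixed p whether they change in either direction, and neither compares the list with other genes. Counts of list members were taken over all genes tested and again with p-values adjusted over the list alone. Genes named in the text follow a rule that was also fixed: per pairwise comparison the 8 largest rises and the 8 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups; 5 each way for the interaction; up to 4 members with the smallest adjusted p of each called list; and the 14 genes of interest. The rule spoke of protein-coding genes, but the count table gives no gene type, so that part was not applied.

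The alternatives were relative log expression and upper quartile scaling, no filter on low counts, DESeq2, limma-voom, a fit of only the groups compared, leaving out each library in turn, and the replicate number as a block. A further 2 alternatives were chosen after the data were seen, because 1 Control library and 1 DAC+OSI library stood apart from their groups: a fit without both, called the 10-library fit, and a correction for the trend with gene GC content. The correlation and covariance of fold changes between comparisons that share the Control libraries were set against 20 simulations in which no gene changed. The splits of the 6 libraries of each pairwise comparison were all counted, and 60 splits of the 12 libraries were drawn for the interaction. Their number was set by run time after a first, larger draw had been seen, which gave the same highest count among the other splits.

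The fit was checked on counts simulated from the mean levels, dispersions and sizes of these libraries, with 200 genes changed. In the design of OSI against Control, edgeR recovered 3% of the genes changed 1.5-fold, 58.2% of those changed 2-fold and 100% of those changed 4-fold. For the interaction these shares were 0%, 7.5% and 84.8%. The adjusted p depends on how many genes change, so these shares hold for 200 changed genes only. The real comparisons gave between 608 and 5860 calls, and their shares may be higher. In the pairwise comparisons between 2.9% and 7% of its calls were false, and 12.9% (9 of 70) in the interaction. With limma-voom the share ran from 2.9% to 12.9%, again highest in the interaction, and with DESeq2 from 18.6% to 32.3%. In each comparison camera called the 1 simulated list of 30 changed genes and 0 of 20 unchanged lists. The simulated genes varied independently of each other, so this check cannot show whether the preset correlation of camera is large enough for real lists. The comparisons with DAC+OSI, the interaction included, shared the same simulated counts.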

Results

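Messenger RNA was sequenced in 12 libraries of PC9-OR cells, a derivative of the established non-small cell lung cancer line PC9 named for its resistance to osimertinib. Osimertinib (OSI) inhibits the receptor tyrosine kinase EGFR, on whose activating mutation PC9 cells depend, and dauricine (DAC) is a plant alkaloid. The groups were Control, OSI, DAC and both compounds together (DAC+OSI), with 3 libraries each. Doses and exposure times are not stated in the labels. Total counts, in mega-counts (M), were 60.9, 43.2 and 42.1 M in Control, 41.1, 46.4 and 47.6 M in OSI, 53.3, 57.0 and 49.2 M in DAC, and 54.1, 24.9 and 66.9 M in DAC+OSI. Genes of the mitochondrial genome took between 10.39% (DAC 3) and 18.56% (OSI 3) of the counts.

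Control 2 and DAC+OSI 2 stood apart from their groups along gene GC content. Across genes, which are not independent replicates, the deviation of a library from its group mean followed GC content with a Spearman rho of 0.56 in Control 2 and 0.57 in DAC+OSI 2. It was between -0.52 and -0.37 in the other libraries of these groups, and between -0.09 and 0.06 in the OSI and DAC libraries. Each comparison below holds at least one of these libraries, so counts from the 10-library fit, which leaves both out, stand beside the counts from all libraries. Its counts were higher in all 6 comparisons. Both libraries were left out because they deviate from their groups, which by itself tends to lower the spread that all comparisons share. The higher counts and smaller p-values of that fit are therefore no independent support for a call. Of the 390 calls of named genes in pairwise comparisons, 388 had every library of one group above every library of the other, which chance would give for 10% of genes and which the rule for the largest changes requires. Those given with a fold below are among the 388. The other calls, of ACSL4 and FTH1 in DAC+OSI against Control, are given below as levels in each library.

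**Figure D1:**
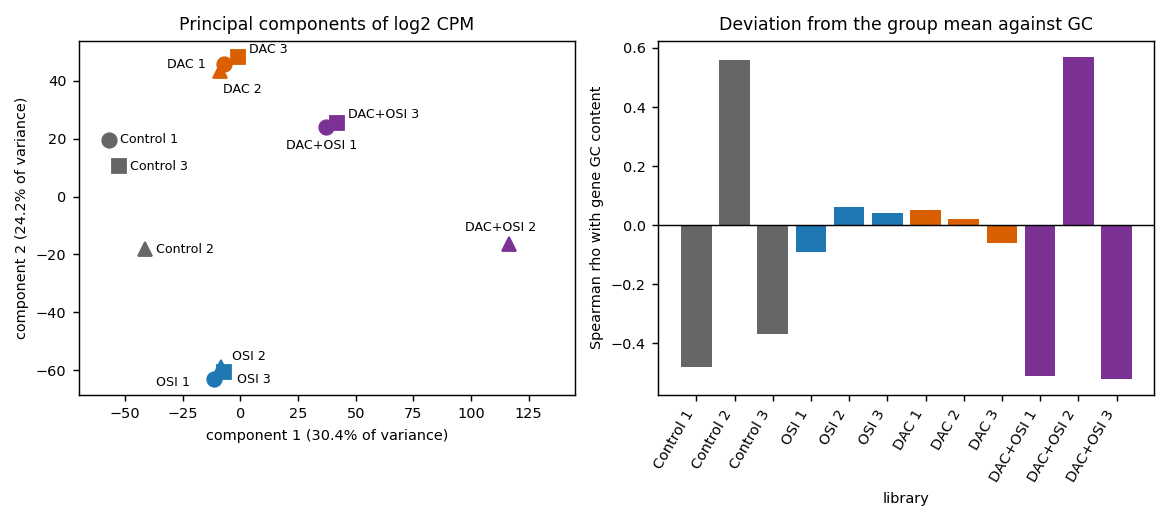
Left, the 12 libraries on the first principal components of log2 CPM, which hold 30.4% and 24.2% of the variance; right, Spearman rho across genes between each library's deviation from its group mean and gene GC content. Control 2 and DAC+OSI 2 reach a rho of 0.56 and 0.57.

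OSI against Control asks what the EGFR inhibitor does by itself in the resistant cells. Feedback regulators and ligands that the MAPK pathway switches on downstream of EGFR fell. DUSP6, a phosphatase that inactivates ERK, fell 3.62-fold, from 215 ± 8.0 to 59.3 ± 7.45 counts per M counts of the library (CPM; mean ± SD, n = 3; adjusted p = 3.2e-06), and the ERK pathway inhibitor SPRY4 fell 2.86-fold, from 107 ± 11.7 to 37.5 ± 1.75 CPM (adjusted p = 5.99e-06). The EGFR ligand genes EREG and HBEGF fell 3.58-fold and 2.65-fold. EGFR itself fell 1.69-fold, from 2261 ± 172 to 1339 ± 158 CPM (adjusted p = 0.00124). Of 25 measured members of the MAPK output list 20 fell and 1 rose, or 21 and 1 adjusted over the list alone, with a median log2 fold change of -0.92 (camera adjusted p = 4e-17).

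Genes of the G1/S transition and DNA replication rose with OSI. E2F1, a transcription factor of S-phase entry, rose 6.21-fold, from 11.2 ± 1.6 to 69.5 ± 4.73 CPM (SD, n = 3; adjusted p = 9.83e-06). RRM2, a subunit of ribonucleotide reductase, rose 2.48-fold to 180 ± 9.19 CPM, the replicative helicase subunit MCM4 2.12-fold to 129 ± 3.12 CPM, and the DNA ligase LIG1 2.47-fold to 60.4 ± 3.12 CPM. In this list 31 of 36 members rose and 0 fell, or 34 and 0 adjusted over the list alone, with a median of 1.01 (camera adjusted p = 1.85e-25). In the G2/M and mitosis list 14 of 38 members rose and 0 fell, or 15 and 0 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.000162, and adjusted p = 0.432 with an estimated correlation). The number was 7 without Control 2, 7 without Control 3, 6, 4 and 7 without OSI 1, OSI 2 and OSI 3, and 23 in the 10-library fit. In the DNA damage repair list 13 of 26 members rose and 0 fell, or 15 and 0 adjusted over the list alone, among them the recombination factor RAD54L (2.57-fold, adjusted p = 5.92e-05). That list had a camera adjusted p of 2.91e-06, and an adjusted p = 0.432 with an estimated correlation.

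Targets of ATF4, the transcription factor of the integrated stress response, fell with OSI. The tryptophan tRNA ligase WARS1 fell 2.99-fold, from 286 ± 32.8 to 95.6 ± 2.46 CPM (SD, n = 3; adjusted p = 3.22e-06), the glycoprotein hormone STC2 2.41-fold and the pseudokinase TRIB3 2.34-fold. Of 34 targets 24 fell and 0 rose, or 27 and 1 adjusted over the list alone, with a median of -0.82 (camera adjusted p = 7.69e-14, and adjusted p = 0.0868 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell 2.2-fold to 335 ± 13.5 CPM (adjusted p = 3.21e-05). In the antigen presentation list 9 of 14 members rose and 1 fell, or 11 and 1 adjusted over the list alone, with a camera adjusted p = 0.000265 and an adjusted p = 0.161 with an estimated correlation. Its member B2M, the light chain of class I molecules, rose 1.88-fold to 428 ± 26.8 CPM (adjusted p = 0.000556), while the peptide transporter subunit TAP2 fell 1.83-fold to 16.4 ± 1.6 CPM (adjusted p = 0.00245).

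Among the largest changes with OSI, the interleukin 33 receptor IL1RL1 fell 14.3-fold, from 179 ± 16.5 to 12.5 ± 2.0 CPM (SD, n = 3; adjusted p = 8.72e-08), and the matrix protein TNC 11.8-fold, from 154 ± 43.2 to 13.0 ± 1.09 CPM. The placental alkaline phosphatase ALPP, whose reads its close relative ALPG could share, rose 28.5-fold, from 8.67 ± 0.897 to 248 ± 22.6 CPM (adjusted p = 9.77e-09), and the keratin KRT4 17.7-fold to 24.1 ± 4.01 CPM.

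Of the genes tied to ferroptosis, a form of cell death driven by lipid peroxides and iron, the transferrin receptor TFRC rose 1.8-fold with OSI to 241 ± 2.51 CPM (SD, n = 3; adjusted p = 0.00173). The cystine transporter SLC7A11 fell 2.1-fold, from 382 ± 91 to 182 ± 11.4 CPM (adjusted p = 0.00744), the polyamine oxidase SMOX 2.62-fold, from 129 ± 30.4 to 49.2 ± 1.09 CPM (adjusted p = 0.000544), and HMOX1, which releases iron from haem, 1.68-fold, from 25.5 ± 1.29 to 15.2 ± 1.08 CPM (adjusted p = 0.00141). GPX4, the enzyme that reduces lipid peroxides, had 337 ± 52.8 CPM in Control and 568 ± 22.6 CPM in OSI, with every OSI library above every Control library and a log2 fold change of 0.76 ± 0.27 (SE; adjusted p = 0.0682). It was called in the 10-library fit (0.89, adjusted p = 1.77e-08), in a range up to 0.233 over the alternatives. The acyl-CoA ligase ACSL4, which loads polyunsaturated fatty acids, had a log2 fold change of -0.59 ± 0.28 (SE; adjusted p = 0.171), and of -0.81 in the 10-library fit (adjusted p = 4.68e-08, in a range up to 0.434 over the alternatives). SAT1, the acetyltransferase of polyamine breakdown named in the series title, had a log2 fold change of 0.17 ± 0.20 (SE; adjusted p = 0.63).

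In all, 3926 genes were called with OSI, 2212 higher and 1714 lower, against 9076 in the 10-library fit. Camera called 17 of 44 lists, of which MAPK output (adjusted p = 0.00905) and G1/S and DNA replication (adjusted p = 0.00374) hold with an estimated correlation. The 15 other lists had an adjusted p between 0.0868 and 0.886 with an estimated correlation. The list of xenobiotic response genes lay at the threshold of 0.05 after rounding and is not among the 17.

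DAC against Control asks what dauricine does by itself. The enzymes of cholesterol synthesis rose together. HMGCS1, which makes the precursor of mevalonate, rose 17-fold, from 42.2 ± 8.54 to 718 ± 52.9 CPM (SD, n = 3; adjusted p = 3.1e-07). ACAT2 rose 13.1-fold to 250 ± 28.6 CPM, the squalene epoxidase SQLE 11.5-fold to 388 ± 34.6 CPM, and INSIG1, an inhibitor of the same pathway, 7.43-fold to 140 ± 11.1 CPM. Of 26 members 24 rose and 0 fell, also adjusted over the list alone, with a median log2 fold change of 2.73 (camera adjusted p = 4.99e-112). In fry the adjusted p was 5.93e-08, and 3.29e-09 for a change in either direction.

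Fatty acid synthesis rose with DAC too. The desaturase SCD rose 6.37-fold, from 1432 ± 135 to 9128 ± 552 CPM (SD, n = 3; adjusted p = 3.1e-07), and ACSS2, which makes acetyl-CoA from acetate, 6.39-fold to 842 ± 97.2 CPM (adjusted p = 2.99e-07). In this list 13 of 15 members rose and 0 fell, also adjusted over the list alone, with a median of 1.48 (camera adjusted p = 8.42e-47). The list of ferroptosis drivers holds enzymes of polyunsaturated lipids and SAT1 itself, which the study singled out. Of its 23 members 9 rose and 1 fell, or 11 and 2 adjusted over the list alone, with a median of 0.34 (camera adjusted p = 5.05e-06), and 5 rose without DAC 3. The desaturase FADS2 rose 6.05-fold to 276 ± 17.2 CPM (adjusted p = 1.45e-05), the acyl-CoA ligase ACSL1 4.07-fold to 322 ± 31 CPM (adjusted p = 5.35e-06), and TFRC 2.24-fold to 301 ± 26.8 CPM (adjusted p = 0.000521). Of 27 ferroptosis suppressors 5 rose and 2 fell, or 6 and 3 adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0443, and adjusted p = 0.472 with an estimated correlation). Without Control 1, Control 2 or Control 3 the number that rose was 3, 2 and 2, it was 2 without any 1 of the DAC libraries, and it was 9 in the 10-library fit. The call ended without Control 2 (adjusted p = 0.122), Control 3 (0.083) or DAC 3 (0.0812), with limma-voom (0.126) and with no filter (0.096), in a range from 0.00518 to 0.472 over the alternatives. SCD, given above, and the ferritin gene FTL, given below, were among the suppressors that rose. GSS, an enzyme of glutathione synthesis, was among those that fell, 1.53-fold to 83.6 ± 1.34 CPM (adjusted p = 0.00403).

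SAT1 rose 1.89-fold with DAC, from 73.2 ± 9.88 to 138 ± 13.5 CPM (SD, n = 3; adjusted p = 0.015). The adjusted p was 0.0683 without Control 2 and 0.0767 without DAC 3, with log2 fold changes of 0.79 and 0.81 against 0.91 with all libraries, and it lay between 1.8e-06 and 0.0767 over the alternatives. HMOX1 rose 1.71-fold to 43.7 ± 3.16 CPM (adjusted p = 0.00257). ACSL4 was called higher too, with 266.5, 263.9 and 298.3 CPM in the DAC libraries and 152.1, 80.48 and 134.7 CPM in Control. SMOX fell 2.21-fold, from 129 ± 30.4 to 58.4 ± 3.15 CPM (adjusted p = 0.00472), and EGFR 1.69-fold to 1334 ± 114 CPM (adjusted p = 0.00282). SLC7A11 had a log2 fold change of 0.03 ± 0.24 (SE; adjusted p = 0.952) and GPX4 0.22 ± 0.27 (SE; adjusted p = 0.669). The 10-library fit gave GPX4 0.34 (adjusted p = 0.00207, in a range up to 0.892 over the alternatives).

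Mitosis genes fell with DAC. The kinase PLK1 fell 2.76-fold, from 93.6 ± 13.4 to 33.9 ± 3.15 CPM (SD, n = 3; adjusted p = 0.000228), CKS1B 2.41-fold to 61.1 ± 6.01 CPM, and CDC20, an activator of the anaphase-promoting complex, 2.16-fold to 34.0 ± 1.76 CPM. Of 38 members of the G2/M and mitosis list 23 fell and 0 rose, or 25 and 0 adjusted over the list alone, with a median of -0.70 (camera adjusted p = 6.01e-22), and 36 fell in the 10-library fit. In the NRF2 target list 6 of 29 members rose and 0 fell, also adjusted over the list alone, and 14 rose in the 10-library fit, with a camera adjusted p = 0.00465 and an adjusted p = 0.224 with an estimated correlation. Its member ME1, a source of NADPH, rose 2.53-fold to 164 ± 15.2 CPM (adjusted p = 0.000306). In the iron handling list 7 of 22 members rose and 1 fell, or 7 and 2 adjusted over the list alone, with a camera adjusted p = 0.00762 and an adjusted p = 0.239 with an estimated correlation. The ferritin light chain gene FTL rose 1.73-fold to 4579 ± 50.8 CPM (adjusted p = 0.0011) and the iron importer SLC11A2 1.84-fold to 90.1 ± 6.13 CPM (adjusted p = 0.000551). The autophagy receptor SQSTM1 rose 1.88-fold to 565 ± 19.4 CPM (adjusted p = 0.000146).

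With DAC 1964 genes were called, 1109 higher and 855 lower. Their number was 1120 without Control 2, 1236 without Control 3, 943 without DAC 1, 1114 without DAC 2, 782 without DAC 3, and 5541 in the 10-library fit. Camera called 21 of 44 lists. Cholesterol synthesis (adjusted p = 1.91e-05), fatty acid synthesis (adjusted p = 0.000109), ferroptosis drivers (adjusted p = 0.0113) and G2/M and mitosis (adjusted p = 0.0437) hold with an estimated correlation. The 17 other lists had an adjusted p between 0.141 and 0.523 with an estimated correlation. For the squamous and basal list, in which 3 of 13 members rose, the median of -0.25 and the mean of 0.40 differ in sign, and camera gave a rise (adjusted p = 0.0129, and adjusted p = 0.383 with an estimated correlation). That call ended with limma-voom (adjusted p = 0.177) and with no filter on low counts (0.104), in a range from 0.000569 to 0.383, and the median lay between -0.27 and 0.06 over the alternatives. The small proline-rich gene SPRR3, a marker of squamous cells with close relatives, rose 6.81-fold to 13.4 ± 1.36 CPM (adjusted p = 2.3e-06).

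**Figure D2:**
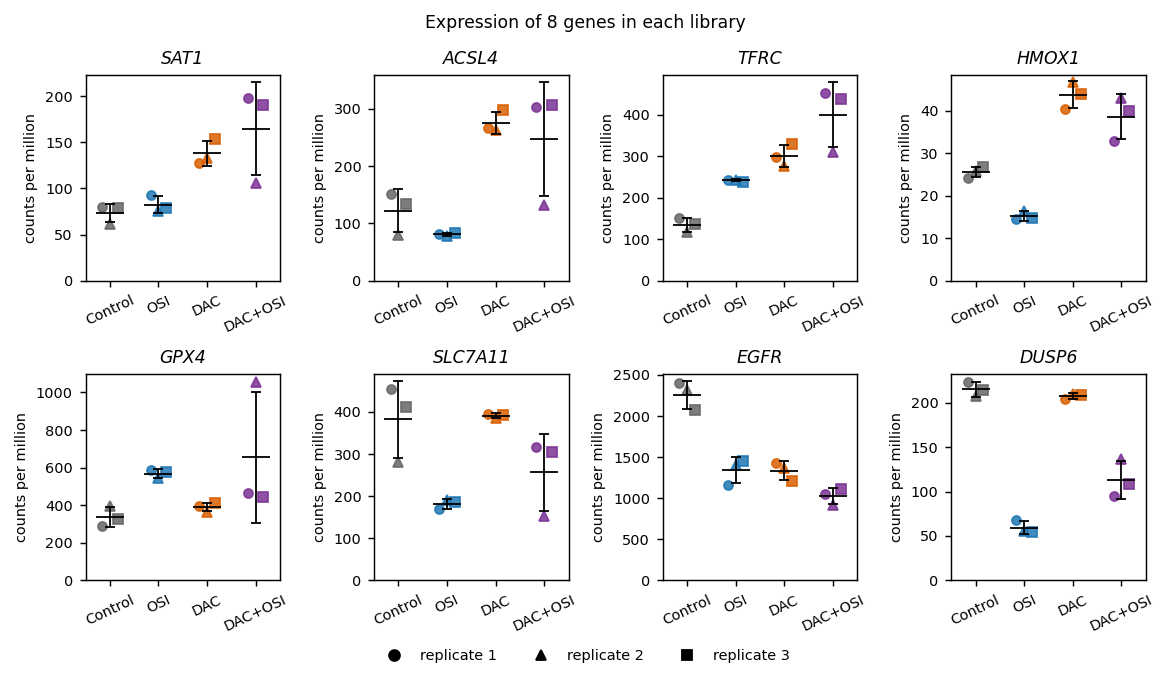
Level in CPM of 8 genes fixed before the data were examined, in each of the 12 libraries (marker shape gives the replicate number), with bars for the group mean ± SD (n = 3). SAT1 and TFRC are highest on average in DAC+OSI, at 165 ± 50.8 and 400 ± 78.7 CPM, and DUSP6 is lowest in OSI, at 59.3 ± 7.45 CPM.

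DAC+OSI against Control asks what the combination does to the resistant cells. Cholesterol and fatty acid synthesis rose and mitosis genes fell. HMGCS1 rose 17.1-fold to 721 ± 192 CPM (SD, n = 3; adjusted p = 9.29e-08), ACAT2 17.4-fold to 332 ± 31.8 CPM, ACSS2 12.3-fold to 1621 ± 222 CPM and SCD 8.16-fold to 11680 ± 1750 CPM. Of 26 cholesterol synthesis genes 24 rose and 0 fell, or 24 and 1 adjusted over the list alone, with a median of 3.20 (camera adjusted p = 1.41e-66). Of 15 fatty acid synthesis genes 13 rose and 0 fell, or 14 and 1 adjusted over the list alone, with a median of 1.84 (camera adjusted p = 9.78e-30). UBE2C, the ubiquitin-conjugating enzyme of mitotic exit, fell 4.89-fold, from 55.0 ± 4.28 to 11.2 ± 1.49 CPM (adjusted p = 2.38e-07), and the spindle checkpoint kinase BUB1B 4.37-fold, from 32.8 ± 1.93 to 7.48 ± 1.01 CPM (adjusted p = 3.13e-07). Of 38 mitosis genes 36 fell and 0 rose, also adjusted over the list alone, with a median of -1.76 (camera adjusted p = 1.37e-45). The mean log2 CPM of this list was 3.72, 3.28 and 3.51 in the DAC+OSI libraries and 5.28, 4.96 and 5.25 in Control, with library 2, which stands apart in GC content, the lowest of each group.

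MAPK output fell and lysosomal genes rose with the combination. FOSL1, a transcription factor induced by ERK, fell 6.08-fold, from 213 ± 41.1 to 35.2 ± 11.9 CPM (SD, n = 3; adjusted p = 4.58e-06), the EGFR ligand gene AREG 4.56-fold to 4.77 ± 1.23 CPM (adjusted p = 9.19e-06), and DUSP6 1.89-fold to 113 ± 21.4 CPM (adjusted p = 0.000352). In this list 17 of 25 members fell and 0 rose, or 19 and 0 adjusted over the list alone, with a median of -0.92 (camera adjusted p = 8.05e-12). The lysosomal sialidase NEU1 rose 5.1-fold, from 41.1 ± 5.55 to 210 ± 25.3 CPM (adjusted p = 1.99e-07), and the protease genes CTSF and CTSD 4.15-fold and 2.28-fold. Of 39 lysosome genes 27 rose and 1 fell, or 29 and 1 adjusted over the list alone, with a median of 0.76 (camera adjusted p = 2.22e-11). Camera also called this list higher against Control with each compound alone. Its median was 0.44 with OSI and 0.33 with DAC (camera adjusted p = 0.0868 and 0.221 with an estimated correlation). The interaction of the lysosome list was not called (camera adjusted p between 0.263 and 0.965 over the alternatives). In the G1/S and DNA replication list 11 of 36 members fell and 1 rose, or 16 and 2 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.00197, and adjusted p = 0.234 with an estimated correlation), and 22 fell without DAC+OSI 2 and 22 in the 10-library fit. In the DNA damage repair list 15 of 26 members fell and 0 rose, or 19 and 0 adjusted over the list alone, with a camera adjusted p = 1.07e-06 and an adjusted p = 0.341 with an estimated correlation.

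Of 23 ferroptosis drivers, SAT1 included, 13 rose and 1 fell with DAC+OSI, also adjusted over the list alone, with a median of 0.72 (camera adjusted p = 8.03e-06). TFRC rose 2.98-fold to 400 ± 78.7 CPM (SD, n = 3; adjusted p = 9.44e-06), FADS2 11-fold to 500 ± 189 CPM (adjusted p = 4.25e-07) and the phospholipid-remodelling enzyme LPCAT3 2.1-fold to 47.2 ± 2.24 CPM (adjusted p = 7.19e-05). SAT1 rose 2.25-fold to 165 ± 50.8 CPM (adjusted p = 0.00102), while SMOX fell 2.6-fold to 49.7 ± 16.4 CPM (adjusted p = 0.000352). HMOX1 rose 1.51-fold to 38.6 ± 5.25 CPM (adjusted p = 0.00404), a call that ended with only the groups compared (adjusted p = 0.0627, in a range down to 0.000199 over the alternatives). ACSL4 and FTH1 were called higher as well, but their DAC+OSI libraries overlapped those of Control. ACSL4 had 302.6, 132.7 and 306.8 CPM in DAC+OSI and 152.1, 80.48 and 134.7 CPM in Control. FTH1 had 7669, 19140 and 5204 CPM in DAC+OSI and 3105, 5521 and 3397 CPM in Control. Of the 8 genes of polyamine catabolism, SAT1 among them, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.917). SLC7A11 had a log2 fold change of -0.57 ± 0.24 (SE; adjusted p = 0.0936), which was -0.77 without Control 2 (adjusted p = 0.0322) and -0.76 without DAC+OSI 1 (adjusted p = 0.0414), in a range from 5.28e-05 to 0.239 over the alternatives.

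GPX4 rose 1.95-fold with DAC+OSI, from 337 ± 52.8 to 655 ± 349 CPM (SD, n = 3; adjusted p = 0.0173), with 464, 1058 and 442.9 CPM in the DAC+OSI libraries. Its log2 fold change of 0.96 rests in part on DAC+OSI 2, without which it was 0.40 (adjusted p = 0.0169), and it was 0.56 in the 10-library fit. Its call ended without Control 1 (adjusted p = 0.0826) or Control 3 (0.0722) and with only the groups compared (0.122), in a range from 1.33e-06 to 0.122 over the alternatives. Of 27 ferroptosis suppressors, GPX4 included, 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.274), with a median of -0.07 and a mean of 0.28, which differ in sign. Camera called that list higher without DAC+OSI 2 (adjusted p = 0.0398) and in the 10-library fit (adjusted p = 0.0182), in a range up to 0.728 over the alternatives. EGFR fell 2.2-fold to 1028 ± 95.2 CPM (adjusted p = 3.42e-05).

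The melanosome and lysosome glycoprotein GPNMB, among the 8 largest rises for DAC+OSI against Control but not the largest, rose 55-fold from 0.83 ± 0.207 to 46.1 ± 3.87 CPM (adjusted p = 3.97e-09). IL1RL1 fell 16-fold to 11.2 ± 1.5 CPM (adjusted p = 1.7e-08). In all, 5860 genes were called, 3198 higher and 2662 lower, against 8778 in the 10-library fit. Camera called 14 of 44 lists. Cholesterol synthesis (adjusted p = 3.34e-05), fatty acid synthesis (adjusted p = 0.000283), G2/M and mitosis (adjusted p = 0.00492), ferroptosis drivers (adjusted p = 0.00754), lysosome (adjusted p = 0.01) and MAPK output (adjusted p = 0.0159) hold with an estimated correlation, and the 8 other lists had an adjusted p between 0.234 and 0.476.

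**Figure D3:**
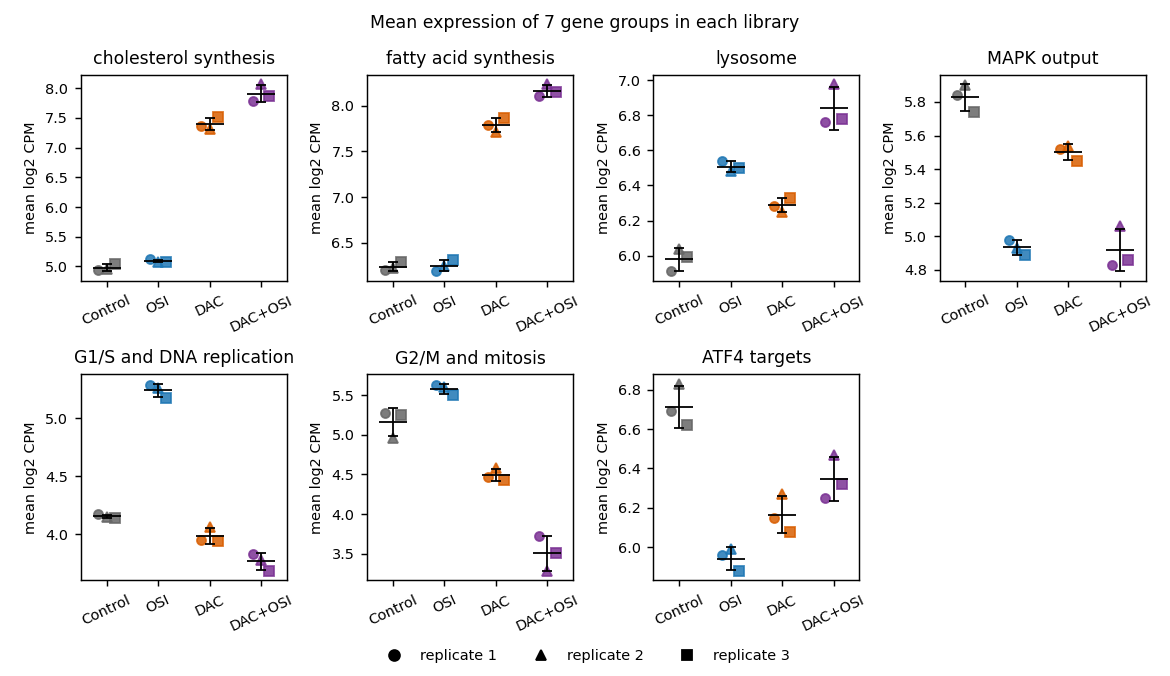
Mean log2 CPM over the members of 7 gene lists in each of the 12 libraries, by group, with marker shape for the replicate number. The DAC and DAC+OSI libraries lie between 7.32 and 8.07 for cholesterol synthesis, all above the Control and OSI libraries, and the DAC+OSI libraries lie between 3.28 and 3.72 for G2/M and mitosis, below all others.

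DAC+OSI against OSI asks what dauricine adds in cells that receive osimertinib. Mitosis genes and replication genes fell. KIF20A, a kinesin of cell division, fell 7.26-fold, from 64.1 ± 3.25 to 8.86 ± 1.13 CPM (SD, n = 3; adjusted p = 5.05e-08), and RRM2 4.78-fold, from 180 ± 9.19 to 37.6 ± 3.81 CPM (adjusted p = 1.78e-07). In the G2/M and mitosis list 36 of 38 members fell and 0 rose, or 37 and 0 adjusted over the list alone, with a median of -2.28 (camera adjusted p = 1.45e-95). In the G1/S and DNA replication list 35 of 36 fell and 0 rose, also adjusted over the list alone, with a median of -1.44 (camera adjusted p = 7.9e-48). RAD54L fell 5.69-fold to 5.22 ± 1.16 CPM (adjusted p = 4.68e-07), and 20 of 26 DNA damage repair genes fell and 0 rose, or 20 and 1 adjusted over the list alone, with a median of -1.28 (camera adjusted p = 1.75e-27).

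ACSS2 rose 17.1-fold over OSI, from 94.7 ± 4.66 to 1621 ± 222 CPM (SD, n = 3; adjusted p = 5.17e-09), and HMGCS1 15.5-fold from 46.6 ± 0.963 CPM (adjusted p = 1.37e-07). In the cholesterol synthesis list 24 of 26 members rose and 0 fell, also adjusted over the list alone, with a median of 3.25 (camera adjusted p = 1.21e-90), and in the fatty acid synthesis list 14 of 15 rose and 0 fell, also adjusted over the list alone, with a median of 1.76 (camera adjusted p = 1.11e-43). Of the ferroptosis drivers 12 of 23 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.78e-07). ACSL4 rose 3.05-fold, from 81.2 ± 2.63 to 247 ± 99.3 CPM (adjusted p = 0.00182). SAT1 rose 2.0-fold, from 82.3 ± 8.93 to 165 ± 50.8 CPM (adjusted p = 0.00491), and HMOX1 2.53-fold, from 15.2 ± 1.08 to 38.6 ± 5.25 CPM (adjusted p = 1.42e-05). In the histone list 7 of 12 members rose and 1 fell, also adjusted over the list alone, with a median of 0.98 (camera adjusted p = 0.000104). The libraries were enriched for poly(A), so these counts cover polyadenylated histone messages only, which need not follow all histone messages. H2AC6 rose 2.73-fold to 106 ± 2.13 CPM (adjusted p = 1.32e-06), and the replication-independent variant H2AZ1 fell 2.33-fold to 20.6 ± 2.02 CPM (adjusted p = 4.07e-05).

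TRIB3 rose 2.78-fold over OSI to 427 ± 81.9 CPM (SD, n = 3; adjusted p = 3.1e-05), VEGFA, the endothelial growth factor, 2.81-fold to 300 ± 39.7 CPM (adjusted p = 3.71e-06), and HSPA5 2.09-fold to 701 ± 51.9 CPM (adjusted p = 4.69e-05). DUSP6 rose 1.91-fold over OSI to 113 ± 21.4 CPM (adjusted p = 0.00055). In all, 3533 genes were called, 1875 higher and 1658 lower. Their number was 2315 without OSI 1, 2209 without OSI 2, 5836 without DAC+OSI 2, and 8730 in the 10-library fit. Camera called 14 of 44 lists. Cholesterol synthesis (adjusted p = 1.43e-05), fatty acid synthesis (adjusted p = 5.09e-05), G1/S and DNA replication (adjusted p = 0.000131), G2/M and mitosis (adjusted p = 0.000298), ferroptosis drivers (adjusted p = 0.00361), histones (adjusted p = 0.0143) and DNA damage repair (adjusted p = 0.0143) hold with an estimated correlation, and the 7 other lists had an adjusted p between 0.205 and 0.461.

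DAC+OSI against DAC asks what osimertinib adds in cells that receive dauricine. MAPK output and mitosis genes fell and lysosomal genes rose. The ephrin receptor EPHA4 fell 3.32-fold, from 82.6 ± 2.42 to 24.8 ± 5.98 CPM (SD, n = 3; adjusted p = 8.26e-05), AREG 2.88-fold, from 14.0 ± 1.48 to 4.77 ± 1.23 CPM (adjusted p = 0.000659), and DUSP6 1.83-fold, from 207 ± 3.14 to 113 ± 21.4 CPM (adjusted p = 0.00193). Of 25 MAPK output genes 13 fell and 0 rose, also adjusted over the list alone, with a median of -0.49 (camera adjusted p = 1.73e-10). The cyclin CCNB2 fell 2.28-fold, from 21.5 ± 1.51 to 9.45 ± 0.646 CPM (adjusted p = 4.37e-05), and 32 of 38 mitosis genes fell and 0 rose, or 34 and 0 adjusted over the list alone, with a median of -1.10 (camera adjusted p = 1.04e-32). CTSF rose 2.87-fold, from 32.8 ± 3.8 to 94.3 ± 10 CPM (adjusted p = 1.55e-05), and NEU1 2.25-fold to 210 ± 25.3 CPM (adjusted p = 0.000194). Of 39 lysosome genes 16 rose and 0 fell, or 24 and 1 adjusted over the list alone, with a median of 0.57 (camera adjusted p = 7.16e-11). The number that rose was 9 without DAC 1, 8 without DAC 2, 9 without DAC 3 and 33 in the 10-library fit.

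The sterol regulator INSIG1 rose 2.2-fold over DAC, from 140 ± 11.1 to 309 ± 55 CPM (SD, n = 3; adjusted p = 0.000559), and ACSS2 1.93-fold, from 842 ± 97.2 to 1621 ± 222 CPM (adjusted p = 0.00056). Cholesterol synthesis as a list had a median of 0.46 (camera adjusted p = 2.72e-06, and adjusted p = 0.0654 with an estimated correlation). Of its 26 members 9 rose and 0 fell, or 16 and 0 adjusted over the list alone, and 4, 4 and 5 rose without DAC 1, DAC 2 and DAC 3 and 22 in the 10-library fit. NLRC5, the transactivator of class I antigen presentation genes, rose 3.65-fold, from 33.5 ± 3.26 to 122 ± 41.7 CPM (adjusted p = 0.000276). The zinc transporter SLC30A2 rose 30.6-fold, from 0.319 ± 0.125 to 9.95 ± 2.0 CPM (adjusted p = 1.48e-06), and FERMT1, an adaptor of integrins, fell 5.53-fold, from 233 ± 17.6 to 42.0 ± 6.79 CPM (adjusted p = 1.6e-06). SAT1 had a log2 fold change of 0.26 ± 0.20 (SE; adjusted p = 0.451). Without DAC+OSI 2, whose SAT1 level of 106.2 CPM was below the 197.4 and 190.7 CPM of the other DAC+OSI libraries, it was 0.49 (adjusted p = 0.0146), and it was 0.49 in the 10-library fit and 0.41 with the GC correction (adjusted p = 0.000231 and 0.0229, in a range up to 0.741 over the alternatives). In all, 2211 genes were called, 1269 higher and 942 lower. Their number was 1073 without DAC 1, 1022 without DAC 2, 1216 without DAC 3, and 5092 in the 10-library fit. Camera called 13 of 44 lists. Lysosome (adjusted p = 0.0282), G2/M and mitosis (adjusted p = 0.0282) and MAPK output (adjusted p = 0.0369) hold with an estimated correlation, and the 10 other lists had an adjusted p between 0.0654 and 0.605.

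**Figure D4:**
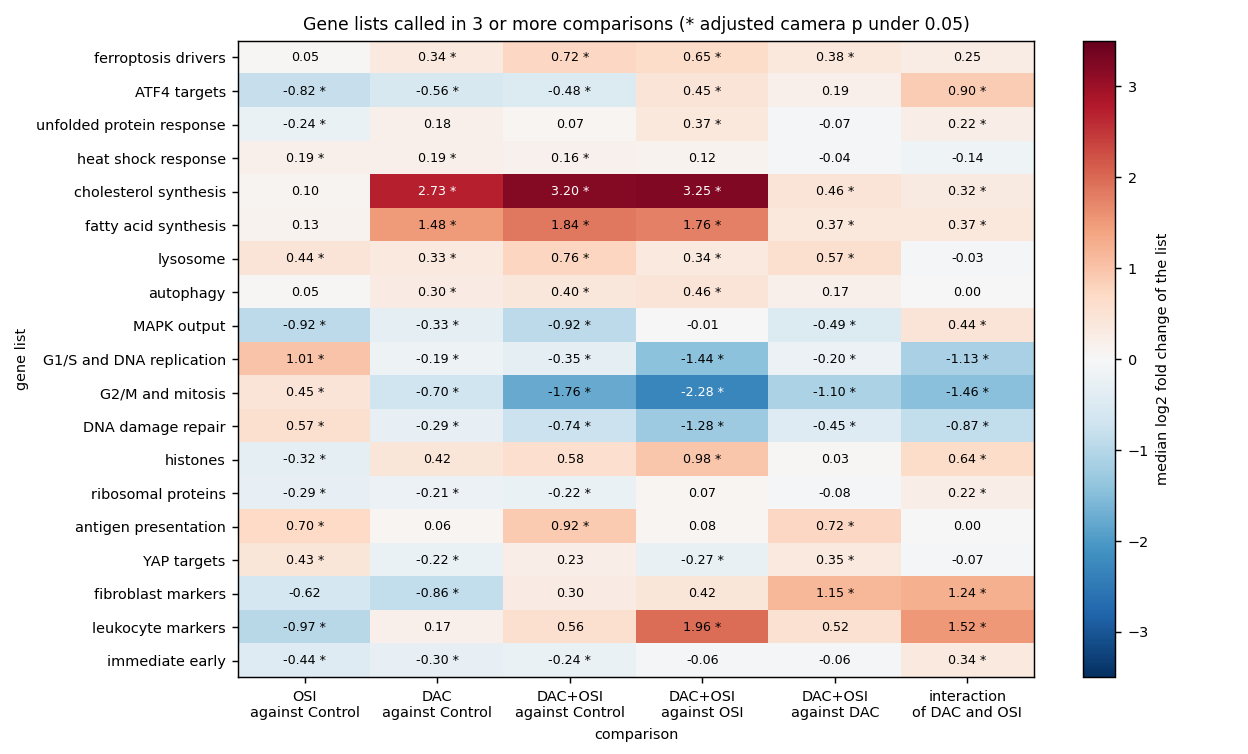
Median log2 fold change of the tested members of 19 gene lists, those called in at least 3 comparisons, in each of the 6 comparisons; a star marks a camera adjusted p under 0.05 at the preset correlation. G2/M and mitosis runs from 0.45 in OSI against Control to -2.28 in DAC+OSI against OSI.

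The interaction asks whether dauricine acts differently in the presence of osimertinib than without it. The lists with the smallest p were those of the cell cycle. RRM2 was 2.48-fold higher in OSI than in Control and 1.93-fold lower in DAC+OSI than in Control, and its interaction was -1.96 ± 0.17 on the log2 scale (SE; adjusted p = 0.000151). KIF20A had an interaction of -2.08 ± 0.18 (SE; adjusted p = 0.000151), with 34.8 ± 2.46, 64.1 ± 3.25, 20.2 ± 1.22 and 8.86 ± 1.13 CPM in Control, OSI, DAC and DAC+OSI (SD, n = 3). The interaction was called negative in 27 of 38 mitosis genes and positive in 0, or 35 and 0 adjusted over the list alone, with a median of -1.46 (camera adjusted p = 2.81e-59). In the G1/S and DNA replication list it was negative in 22 of 36 genes and positive in 0, or 31 and 0 adjusted over the list alone, with a median of -1.13 (camera adjusted p = 4.81e-49), and negative in 35 without DAC+OSI 2 and 36 in the 10-library fit. In the DNA damage repair list it was negative in 11 of 26 genes and positive in 0, or 17 and 0 adjusted over the list alone, with a camera adjusted p = 1.25e-22 and an adjusted p = 0.0612 with an estimated correlation. That number was 7 without OSI 2, 7 without DAC 2 and 19 in the 10-library fit.

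Against Control, ATF4 targets fell with DAC and with DAC+OSI as well as with OSI. With DAC 15 of 34 fell and 1 rose, or 19 and 2 adjusted over the list alone, with a median of -0.56 (camera adjusted p = 2.02e-10, and adjusted p = 0.141 with an estimated correlation). The number that fell was 9 without Control 2, 9 without DAC 1, 5 without DAC 3 and 25 in the 10-library fit. With DAC+OSI 14 fell and 3 rose, or 15 and 3 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.00679, and adjusted p = 0.476 with an estimated correlation), and 23 fell in the 10-library fit.

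ATF4 targets had a positive interaction. VEGFA had 250 ± 24.5, 107 ± 3.2, 217 ± 6.42 and 300 ± 39.7 CPM in Control, OSI, DAC and DAC+OSI (SD, n = 3), and an interaction of 1.69 ± 0.17 on the log2 scale (SE; adjusted p = 0.000345). TRIB3 had an interaction of 1.48 ± 0.22 (SE; adjusted p = 0.00325) and WARS1 of 1.32 ± 0.17 (SE; adjusted p = 0.00138). It was called positive in 12 of 34 targets and negative in 0, or 27 and 0 adjusted over the list alone, with a median of 0.90 (camera adjusted p = 1.73e-26). The number over all genes was 6 without OSI 1, 7 without OSI 3, 7 without DAC 1, 6 without DAC 3, 22 without DAC+OSI 2 and 27 in the 10-library fit. KLHDC7B, a gene of the kelch family, had an interaction of 3.62 ± 0.32 (SE; adjusted p = 0.000151), and the protease gene FAM111B one of -2.66 ± 0.29 (SE; adjusted p = 0.000424). SAT1 had an interaction of 0.09 ± 0.29 (SE; adjusted p = 0.927), and of 0.43 in the 10-library fit (adjusted p = 0.0179, in a range up to 1.0 over the alternatives).

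In all, 608 genes had a called interaction, 211 positive and 397 negative, so that 34.7% were positive. Without a filter on low counts 1354 were called and 58% were positive, so the balance depends on that filter, and 48.7% were positive in the 10-library fit. Their number was 334, 340 and 363 without OSI 1, OSI 2 and OSI 3, 343, 346 and 330 without DAC 1, DAC 2 and DAC 3, 1463 without DAC+OSI 2, and 4339 in the 10-library fit. In the simulated check 12.9% of the interaction calls were false, the highest share of the 6 comparisons with edgeR. Camera called 17 of 44 lists. G1/S and DNA replication (adjusted p = 0.000374), G2/M and mitosis (adjusted p = 0.00401) and ATF4 targets (adjusted p = 0.015) hold with an estimated correlation, and the 14 other lists had an adjusted p between 0.0612 and 0.741.

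The drug-alone comparisons and the combination share the 3 Control libraries, which by itself makes their fold changes correlate. With DAC and with DAC+OSI, 1693 genes were called in the same direction, 996 higher, such as HMGCS1 and SCD, and 697 lower, such as PLK1 and SMOX, which is 86.2% of the genes called with DAC. Independent calls would share 170.3 and 109.3, and simulations in which no gene changed, which leave out the effects, shared 0 at the median and 0 at most. Across genes, which are not independent replicates, the fold changes of both comparisons correlated with r = 0.71 and had a covariance of 0.428, against 0.50 and 0.079 in the same simulations, which share the Control libraries. Another 17 genes were called in opposite directions. The number in the same direction was 1120, 1013 and 1083 without Control 1, Control 2 and Control 3. With OSI and with DAC+OSI, 2387 genes were called in the same direction, 1353 higher, such as CTSF and GPNMB, and 1034 lower, such as IL1RL1 and AREG, against 339.8 and 219.1 from independent calls and a median of 0 and at most 1 in the simulations. Here r was 0.54 and the covariance 0.393, against 0.49 and 0.078 in the simulations. Another 181 genes, RRM2 and KIF20A among them, were called in opposite directions. With OSI and with DAC, 795 genes were called in the same direction, 459 higher and 336 lower, against 117.8 and 70.4 from independent calls. Another 147 were called in opposite directions. For these comparisons r was 0.33, below the 0.50 of the simulations, and the covariance was 0.17, against 0.078. The 3 Control libraries cannot be divided so that each comparison keeps at least 2 of its own, which was therefore not tried, and part of each overlap may come from sharing them.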

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

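The tests of Control 2 and DAC+OSI 2, the 60 splits for the interaction, and the tests of the GC trend, which use the 10-library fit and the GC correction, were chosen or set only after the data or the result were seen. The gene lists and genes of the next 2 paragraphs were singled out by the test of the interaction, that is, of the difference between the effect of dauricine in the presence of osimertinib and its effect without it, and the 3 patterns after them come from the other comparisons and from the libraries themselves.

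Among gene lists, the median interaction on the log2 scale was -1.46 for G2/M and mitosis, -1.13 for G1/S and DNA replication, -0.87 for DNA damage repair, -0.32 for glutathione metabolism and -0.22 for NRF2 targets. It was 0.90 for ATF4 targets, 0.22 for the unfolded protein response, 0.32 for cholesterol synthesis, 0.37 for fatty acid synthesis, 0.44 for MAPK output, 0.64 for histones, 0.22 for ribosomal proteins, 0.34 for NF-kB and inflammation, 0.34 for immediate early genes, 0.42 for mesenchymal genes, 1.24 for fibroblast markers and 1.52 for leukocyte markers. G2/M and mitosis, G1/S and DNA replication and ATF4 targets held with an estimated correlation. Without DAC+OSI 2 the median moved to 0 for mesenchymal genes, 0.07 for immediate early genes, 0.17 for NF-kB and inflammation, 0.22 for fatty acid synthesis, 0.52 for fibroblast markers and 0.59 for leukocyte markers. The 10-library fit gave -0.14 for mesenchymal genes, -0.02 for immediate early genes, 0.11 for NF-kB and inflammation, 0.06 for ribosomal proteins, 0.45 for the unfolded protein response, 0.36 for fibroblast markers and 0.71 for leukocyte markers. NF-kB and inflammation had 0.19 without Control 1 and 0.20 without OSI 1, immediate early genes 0.19 without Control 2, and NRF2 targets between -0.14 and -0.09 without any 1 of Control 1, Control 2, OSI 1, DAC 1, DAC+OSI 1 and DAC+OSI 3. Leaving out 1 library ended the call of NRF2 targets (Control 1, OSI 1, DAC 3 or DAC+OSI 3, adjusted p up to 0.0857), ribosomal proteins (Control 2 or OSI 3, up to 0.084), immediate early genes (Control 2 or DAC+OSI 2, up to 0.244), NF-kB and inflammation (Control 1, Control 2, OSI 2, OSI 3, DAC 3 or DAC+OSI 2, up to 0.361) and mesenchymal genes (Control 2, OSI 2, OSI 3, DAC 1, DAC 2 or DAC+OSI 2, up to 0.542).

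Among genes, the interaction was -2.66 for FAM111B, -2.63 for NPNT, -2.62 for CCNE2, -2.46 for RIBC2, -2.45 for MYOZ1, -2.08 for KIF20A, -1.96 for RRM2, -1.81 for BUB1B and -1.23 for MCM4. It was 3.62 for KLHDC7B, 1.69 for VEGFA, 1.34 for DDIT3, 1.32 for WARS1, 0.99 for DUSP6 and 0.85 for CDKN1A. It was 9.99 for COL1A2, 5.27 for ACTA2, 3.23 for COL1A1 and 2.74 for the small cytoplasmic RNA gene RN7SL1, which rest in part on the libraries that stand apart. COL1A2 had 8.0 without DAC+OSI 2, 8.55 without Control 2 and 11.2 without OSI 1, ACTA2 4.53 without Control 2 and RN7SL1 2.02 without DAC+OSI 2, and the 10-library fit gave 6.54, 4.17, 2.3 and 1.85 for the genes in that order. The COL1A2 value rests on few reads, with counts of 7, 3 and 0 in the OSI libraries and 6, 4 and 1 in the DAC libraries. Whether it depends on the prior count was not tested. The limma-voom fit did not call it (adjusted p = 0.159, in a range down to 7.93e-52 over the alternatives). Leaving out 1 library ended the call of CDKN1A (without OSI 1, OSI 2, DAC 1 or DAC 2, adjusted p up to 0.0613), DUSP6 (without OSI 2, OSI 3 or any DAC library, up to 0.0639), RN7SL1 (without Control 2 or any OSI library, DAC 1 or DAC 3, up to 0.0856) and DDIT3 (without any 1 library but Control 2, DAC 2, DAC+OSI 1 and DAC+OSI 2, up to 0.0842), while the 10-library fit called CDKN1A and DDIT3 at 5.32e-05 and 8.19e-06. Of 60 splits of the 12 libraries into groups of the same sizes, 1, the real one, gave 608 genes with a called interaction and the highest other 2. The other splits place the effects of each compound within groups, where they widen the spread and leave few calls with or without an interaction, so these splits do not decide whether chance gave that number.

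Cholesterol synthesis genes rose with DAC, with a median log2 fold change of 2.73 over 26 genes. If the GC trend of single libraries were the cause, the median would drop below 1 in the 10-library fit or with the GC correction. It was 2.64 in the 10-library fit and 2.61 with the GC correction, and so stayed above 1 in both. That argues against the GC trend only. A response of the cells to dauricine stays open as an untested hypothesis. The labels do not say whether the libraries are separate cultures, and other doses were not measured. In the 10 splits of the 6 libraries of this comparison the real one gave 1964 called genes and the highest other 0, with 1 split as large, and 10 splits are too few for a share under 0.05. The other splits also mix libraries of both groups, which widens the spread within groups and leaves few calls. They do not decide whether chance gave that number.

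Mitosis genes fell with DAC+OSI and replication genes rose with OSI, each against Control. The median of mitosis genes in DAC+OSI against Control, -1.76, stayed at -1.68 or below in the 10-library fit and with the GC correction, and that of replication genes in OSI against Control, 1.01, stayed at 1 or above, which argues against the GC trend of single libraries for both. A lower share of polyadenylated short-lived messages in 1 library would lower the mitosis genes in that library alone, but the highest DAC+OSI library lay 1.24 below the lowest Control library in mean log2 CPM of the list. A change in the cycling of the cells under the compounds stays open as an untested hypothesis, since cell counts and cell cycle phases were not measured here. The real split gave 3926 called genes for OSI, 5860 for DAC+OSI against Control, 3533 against OSI and 2211 against DAC, the highest other split 0 each, and again 10 splits are too few for a share under 0.05. Here too the other splits mix libraries of both groups, so they do not decide whether chance gave these numbers.

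Control 2 and DAC+OSI 2 stood apart from the other libraries of their groups. A GC-dependent difference in library preparation or sequencing is a candidate explanation: the smaller rho of these libraries with gene GC content was 0.56, against at most 0.09 in size in the OSI and DAC libraries. Low depth is argued against for Control 2, whose 43.2 M counts exceed the 41.1 M of OSI 1, a library that does not stand apart, but stays open for DAC+OSI 2, whose 24.9 M are the fewest of all. An exchange of the 2 libraries is argued against by cholesterol synthesis, in which DAC+OSI 2 lay 3.12 above Control 2 in mean log2 CPM, while the means of the other libraries of their groups differed by 2.83. No biological explanation was tested, since the design gives none for single libraries.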

How the results depend on the processing

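The 10-library fit and the GC correction were chosen after the data were seen, and all other alternatives before. No named gene or list called in either fit changed direction under either other scaling, DESeq2 (run for the genes only), limma-voom, no filter on low counts, the fit of only the groups compared or the replicate block, while calls changed in both directions: over the 12 fits that leave out 1 library, gene calls ended in 302 cases, began in 45 and kept their side in 3366, and list calls in 58, 38 and 1752. The list calls that ended include those of the xenobiotic list for OSI against Control, which lay at the threshold and is counted as called here only. Relative log expression and upper quartile scaling gave 3885 and 3886 called genes for OSI against Control (3926 with TMM). With the replicate number as a block the counts were 4403, 2408, 6333, 3831, 2688 and 791 in the order OSI, DAC and DAC+OSI against Control, DAC+OSI against OSI and against DAC, and interaction. Correlations of same-numbered deviations ran from -0.063 to 0.431, and 9 of 12 libraries correlated best with their own number, a hint from the data and not from the design. The 3 of 18 pairs over 0.1, the limit set for pairing, were all those of Control with DAC+OSI (0.285, 0.431 and 0.2), where Control 1 with DAC+OSI 3 also had 0.282.

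Counts that moved by over 1.5 times were, for DAC against Control (1964), 2981 with DESeq2, 3241 with only the groups compared, 3826 with the GC correction and 5541 with 10 libraries; for DAC+OSI against DAC (2211), 3394, 797, 3540 and 5092 in the same order; for the interaction (608), 1354 without a filter, 1334 with DESeq2, 1715 with the GC correction and 4339 with 10 libraries; for OSI against Control (3926), 5952 with the GC correction and 9076 with 10 libraries; for DAC+OSI against OSI (3533), 1800 with only the groups compared, 5571 with the GC correction and 8730 with 10 libraries; and for DAC+OSI against Control (5860), 2958 with only the groups compared. Genes shared with the combination numbered 3233 for DAC (1693) and 3601 for OSI (2387) with the GC correction, and 4581 and 4747 with 10 libraries. The cause was not tested. Leaving out 1 library gave 2648 to 3670 for OSI against Control, 782 to 1315 for DAC, 4506 to 7706 for DAC+OSI, 2209 to 5836 against OSI, 1022 to 2834 against DAC and 330 to 1463 for the interaction, and 1013 to 1120 and 1620 to 2201 shared genes for DAC and OSI. The highest counts for DAC+OSI against Control and against OSI and for the interaction came without DAC+OSI 2, and that against DAC without DAC+OSI 1 (2691 without DAC+OSI 2). The causes were not tested. Reversed in DAC+OSI against OSI were GPX4 (0.20), to -0.35 without DAC+OSI 2 and -0.34 with 10 libraries, and SMOX (0.01), to -0.30 with 10 libraries. Reversed in the interaction with 10 libraries were FTH1 (0.45), to -0.58, and the medians of receptor tyrosine kinases (0.33), to -0.15, glycolysis (0.15), to -0.31, and mesenchymal genes (0.42), to -0.14; the cause was not tested. With 200 genes changed in the simulation, changes of 1.5-fold were found in 3% of simulated cases for OSI against Control. The adjusted p depends on how many genes change, and 3926 were called in the real comparison, so its share may be higher.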

Other observations

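Markers of leukocytes and fibroblasts, fixed as signs of other cell types, differed between groups. CSF1R, the receptor of macrophage growth factors, had 20.6 ± 3.63, 31.8 ± 3.0, 45.4 ± 1.89 and 124 ± 57.6 CPM in Control, OSI, DAC and DAC+OSI (SD, n = 3), and rose 3.89-fold in DAC+OSI over OSI (adjusted p = 0.000168). NKG7, a gene of cytotoxic lymphocytes, had 2.48 ± 0.564, 0.752 ± 0.163, 3.87 ± 0.498 and 3.69 ± 1.43 CPM, and rose 4.78-fold in the same comparison (adjusted p = 0.000195). Of 15 leukocyte markers 11 rose and 1 fell there, or 13 and 1 adjusted over the list alone, with a median log2 fold change of 1.96 (camera adjusted p = 4.29e-05, and adjusted p = 0.461 with an estimated correlation). The number was 7 without any 1 of OSI 1, OSI 2 or OSI 3, and the median was 1.12 without DAC+OSI 2 and 1.14 in the 10-library fit. OSI was itself below Control: 5 of the 15 fell and 1 rose there, or 8 and 2 adjusted over the list alone, with a median of -0.97 (camera adjusted p = 0.0451, and adjusted p = 0.85 with an estimated correlation), among them NKG7, which fell 3.3-fold (adjusted p = 0.00131). That call ended without Control 1 (adjusted p = 0.0778), OSI 1 (0.0562) or OSI 3 (0.057), in the 10-library fit (0.0611) and with the GC correction (0.0971), in a range from 0.00419 to 0.85 over the alternatives, and 1 fell without any 1 of Control 1, OSI 1 or OSI 2 and 9 in the 10-library fit. In DAC+OSI against Control the list was not called (2 rose and 1 fell, or 2 and 0 adjusted over the list alone, median 0.56, camera adjusted p = 0.141). It was called there without DAC+OSI 1 (adjusted p = 0.0195) or DAC+OSI 3 (0.0179) and with no filter on low counts (0.0263), in a range up to 0.801 over the alternatives. Of 7 fibroblast markers 2 rose and 0 fell in DAC+OSI against DAC, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.603 with an estimated correlation), a call that ended without DAC+OSI 2 (adjusted p = 0.0767). The number that rose was 1 without DAC 2 or DAC 3 and 3 without DAC+OSI 1. Camera called the same list lower in DAC against Control, where 1 of 7 fell, with a median of -0.86 (adjusted p = 0.523 with an estimated correlation). That call ended without Control 2 (camera adjusted p = 0.132) and in the 10-library fit (0.225). In DAC+OSI against Control the list was not called. The collagen gene COL1A1 had 12.3 ± 4.79, 6.29 ± 1.1, 9.8 ± 0.43 and 47.2 ± 27.6 CPM in the same order of groups, with 25.3, 78.3 and 38.1 CPM in the DAC+OSI libraries.

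MT-CYB, which encodes cytochrome b, fell 1.67-fold with DAC, from 4640 ± 138 to 2770 ± 288 CPM (SD, n = 3; adjusted p = 0.00678). Of 13 genes of the mitochondrial genome 5 fell and 0 rose, or 6 and 0 adjusted over the list alone, with a median of -0.54 (camera adjusted p = 0.000355, and adjusted p = 0.383 with an estimated correlation). The number that fell was 2, 3 and 2 without Control 1, Control 2 and Control 3, 2, 2 and 1 without DAC 1, DAC 2 and DAC 3, and 12 in the 10-library fit. In DAC+OSI against Control 16 of 34 autophagy genes rose and 2 fell, or 17 and 2 adjusted over the list alone (camera adjusted p = 0.000245, and adjusted p = 0.234 with an estimated correlation), and the folliculin partner FNIP2 rose 4.73-fold to 8.71 ± 0.492 CPM (adjusted p = 5.23e-07).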
